A study of Homo sapiens with 2 samples.

How the data were processed

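Single-cell RNA libraries were made from 2 cultures of U251, an established human glioblastoma cell line, grown in RPMI with 10% serum. One culture was labelled ATRX wild type and the other ATRX knockout, with 1 library per group. Per the labels' protocols, 10000 cells and 50000 reads per cell were aimed for, and libraries were sequenced as paired reads on a NovaSeq instrument. How the knockout was made, and whether the kit counts the 3′ or the 5′ end of transcripts, is not given in the sources used here.

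Each deposited matrix held unnormalised counts of unique molecular identifiers (UMIs), as whole numbers per gene and barcode, for 33538 genes and 6794880 barcodes, most of them without a cell. Cell Ranger, Seurat and the genome build hg38 were named without versions, per the submitters' processing notes, and the file headers gave software version 3.1.0. No filter on cells had been applied to the deposited counts. Features were the same in both files. Of these, 33456 were placed on GRCh38 by gene identifier in a GENCODE annotation, which may not be the annotation used by the authors. One gene of the lists had no matching feature.

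Cells were called as barcodes with at least 1/10 of the 99th percentile of UMIs among the 10000 largest barcodes, at least 500 genes and at most 20% mitochondrial UMIs. The UMI minimum was 9053 in the wild type and 13641 in the knockout, and 20 and 14 barcodes were removed for mitochondrial UMIs. Scrublet called 0 cells as doublets in both libraries, so it was treated as not having worked and no doublets were removed. Barcodes from 500 UMIs up to 0.5 times the minimum served as a near-empty profile for free RNA. UMIs were summed over kept cells, scaled to the same total in both libraries (counts per 1e6 UMIs, CPM) and compared as a log2 ratio of knockout over wild type. A count of 0 was set to 3 counts. Genes with a mean of at least 5 CPM were called measured.

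With 1 library per group there is no test between genotypes, and no p-value is given. Intervals are 95% exact intervals (Poisson for sums, Clopper-Pearson for shares, conditional binomial for ratios) and cover counting error only. They leave out differences between cultures, clones and preparations. For each gene list the median log2 ratio of measured members was set against 10000 random lists matched on mean CPM in 20 bins, as a description of these libraries.

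Cell cycle phases were scored with scanpy 1.11.5 on both libraries together, after each cell was thinned to 12000 UMIs. This left out 299 wild-type cells and 0 knockout cells. The S and G2/M lists held 43 and 54 genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and, for TMM factors, edgeR 4.0.16 in R 4.3.3 were used.

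Before the data were examined, 34 gene lists and 3 lists defined by symbol were fixed, as were the genes to be named. These were ATRX and CHEK1, the 12 highest and 12 lowest ratios among genes with at least 20 CPM in the higher library, and up to 4 members of each list with the largest ratio and at least 10 CPM. Mitochondrial, ribosomal protein, sex-linked marker clone-style, LINC and antisense names were left out of the highest and lowest 12. CHEK1 was also to be given within each phase. Some list members and 1 gene list are not reported here. Genes named outside this rule were chosen after their values were seen. Alternatives covered the cell call, the mitochondrial limit, removal of the cells with the most UMIs, 3 other scalings, per-cell means, thinning, equal phase weights, expression minimums and other phase lists.

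The ratio, interval and list steps were tested on simulated counts for the comparison of the 2 libraries, with 200 of 9323 genes changed. Median folds of 1.50, 2.00, 4.00 and 0.499 were recovered for simulated folds of 1.5, 2, 4 and 0.5, and the interval held the true value for 95.0% of unchanged genes. Of 200 random lists, 96.5% lay in the middle 95% of matched lists. A shift of -0.5 simulated on 1 chromosome was recovered as -0.50.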

Results

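Transcripts were counted in single cells of U251, a human glioblastoma line, with wild-type ATRX or with an ATRX knockout. ATRX is a chromatin remodeller that places histone H3.3 in heterochromatin and at telomeres and is often mutated in glioma. The wild-type file held 369368075 UMIs and the knockout file 368225132. Cells were called for 6453 wild-type and 4671 knockout barcodes, against a target of 10000. They carried a median of 35324 and 52948 UMIs and of 5725 and 6766 genes. Near-empty barcodes held a median of 2019 and 1346 UMIs, which was 5.72% and 2.54% of a median cell. Each genotype had 1 library, so every difference below is between 2 libraries and has no replicate check.

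The first comparison asked whether ATRX itself differed between the libraries. ATRX (ENSG00000085224, GRCh38 chromosome X, 77504878 to 77786233, minus strand) was counted at 169 CPM in the wild type and 50.2 CPM in the knockout. The log2 ratio was -1.75 (95% interval -1.78 to -1.72), and 29.7% of the wild-type level remained. In near-empty barcodes ATRX stood at 58.0 and 19 CPM. A mutation that leaves the counted end of the transcript in place need not lower this count, so the lower count goes with the labels without showing what was altered. ATRX was at 166 CPM over the summed counts of 222 of the 4671 knockout-library cells and at 44.3 CPM in the other 4449. These 222 were picked by a ratio of 2 chromosome 3 stretches like that of wild-type cells, not by ATRX in each cell. Below, ATRX near the wild-type level refers to their summed counts.

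The series is about the passage between cell cycle phases, so phases and the checkpoint kinase CHEK1 were compared next. Fewer knockout cells were assigned to G2/M and more to G1. After thinning to 12000 UMIs, 57.8% of 6154 wild-type cells (56.6% to 59.1%) and 35.9% of 4671 knockout cells (34.5% to 37.3%) were called G2/M. G1 held 8.25% (7.58% to 8.97%) and 25.1% (23.9% to 26.4%), and S held 33.9% (32.7% to 35.1%) and 39.0% (37.6% to 40.4%). Without thinning, G2/M held 64.9% and 42.0%, G1 held 7.08% and 20.1%, and S held 28.0% and 37.9%. With the alternative S and G2/M lists, G2/M held 35.7% and 18.97%, G1 held 6.71% and 19.4%, and S held 57.5% and 61.6%. The shares thus depended on the gene lists, which the intervals do not cover, whereas the direction of each difference was kept. An S or G2/M score within 0.05 of 0 was found in 34.6% of wild-type and 28.1% of knockout cells. The value 0 bounds only G1, because S and G2/M are told apart by the higher score. These are therefore not shares of borderline calls, and closeness to the boundary between S and G2/M was not counted. Free RNA, which differed between the libraries, also enters the scores. The calls alone do not show how fast either culture cycled.

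The G2/M genes with which these calls were scored were lower in the knockout, which is therefore not separate support for the calls. The median log2 ratio of these genes was -0.45 over 54 measured members, at percentile 0 of matched random lists, with 17 members at least 1.5-fold lower and 0 at least 1.5-fold higher. CKS2, a subunit of cyclin-dependent kinases, was at 405 and 149 CPM in wild type and knockout. AURKA, a mitotic spindle kinase, was at 109 and 54.7 CPM. RANGAP1, a GTPase-activating protein of Ran, was at 82.6 and 41.7 CPM, and GAS2L3, a cytoskeletal linker, at 18.2 and 8.64 CPM. The alternative G2/M list had a median of -0.42 over 30 genes, with PLK1 at 69.7 and 32.6 CPM, the kinesin KIF20A at 36.8 and 17.1, CCNF at 22.3 and 10.4, and the spindle gene ASPM at 128 and 65.2. With G1, S and G2/M weighted equally, the median of the first G2/M list was -0.14 and that of the alternative list -0.10. Within G1, S and G2/M cells the first list lay at percentiles 36.3, 59.5 and 12.3 of matched random lists. The phases were called from the first list itself, so cells of the same phase are matched on these genes. The values within phases and with equal weights therefore cannot decide whether these genes differ beyond the phase shares. In the 222 cells with ATRX near the wild-type level, of which 57.7% were called G2/M, the medians of the first and alternative lists were -0.07 and -0.16.

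S-phase genes stood near the middle of all genes. The S list had a median of -0.03 over 42 genes (percentile 72.5), which became 0.05 with TMM factors and 0.07 with median-of-ratios factors and was also positive among members of at least 20 CPM. The alternative S list had a median of -0.05 and also turned positive under both scalings and with equal phase weights. Single members went both ways: the helicase subunit MCM6 was at 32.4 and 60.0 CPM and WDR76 at 32.7 and 62.4, whereas RRM2, which makes deoxyribonucleotides, was at 307 and 201, and the exonuclease EXO1 at 23.8 and 15.2, of which RRM2 and EXO1 lay among neighbours shifted by -0.78 and -0.56. DNMT1, the maintenance DNA methyltransferase, was at 263 and 171 CPM, FANCI at 79.0 and 57.2, MCM2 at 57.1 and 41.9, and thymidine kinase TK1 at 201 and 273.

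CHEK1 (ENSG00000149554, chromosome 11, 125625136 to 125676255, plus strand) was at 51.6 CPM in the wild type and 42.8 CPM in the knockout, a log2 ratio of -0.27 (-0.31 to -0.23). With median-of-ratios factors the CHEK1 ratio was -0.17. Within phases it was -0.31 (-0.37 to -0.26) in G2/M cells and -0.17 (-0.23 to -0.11) in S cells, the latter -0.07 with TMM factors. In G1 cells it was -0.13 (-0.27 to 0.02), a difference not detectable at this depth, and TMM factors gave 0.11. CHEK1 was at 39.1 CPM in the 222 cells with ATRX near the wild-type level, a ratio of -0.40 (-0.53 to -0.28), against -0.26 in the other 4449. The 25 measured checkpoint genes had a median of -0.04 (percentile 60.0), which turned positive under TMM and median-of-ratios factors. Among them TP53BP1, a double-strand break sensor, was at 23.5 and 38.5 CPM, and MDC1, RAD1 and TOPBP1 were at 17.2 and 10.3, 49.95 and 32.9, and 45.7 and 34.3 CPM.

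Among the cyclins and their partners, cyclin D1 and cyclin B1 were lower in the knockout and cyclin E1 was higher. CCND1 was at 629 and 309 CPM, CCNB1 at 225 and 126, CCNE1 at 14.1 and 22.9, and the inhibitor CDKN2D at 41.5 and 67.3. The 19 genes had a median of 0.02, whose sign changed under 4 alternatives. Both CCND1 and CCNB1 were closer to the wild-type library in those 222 cells, at 560 and 222 CPM. The CCNE1 ratio was 1.16 in G2/M cells and -0.03 in G1 cells, the latter too near 0 for its sign to be settled under other scalings. CDKN1A, which was chosen after its values were seen, had a ratio of 1.11 in G2/M and -0.93 in G1 cells. The E2F and DREAM list had a median of -0.15 (percentile 24.1), with FOXM1 at 81.2 and 54.3 CPM, E2F4 at 45.8 and 34.3, E2F6, whose neighbours were shifted by -0.71, at 18.1 and 11.2, and E2F2 at 6.92 and 10.5.

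**Figure D1:**
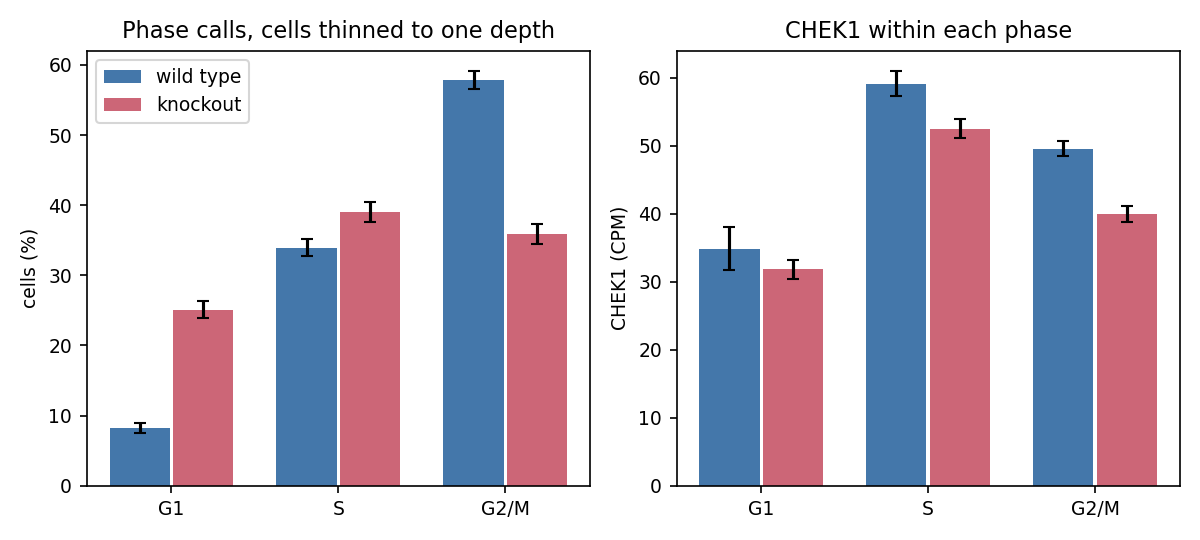
Left, percent of cells called G1, S or G2/M in the wild-type and knockout libraries after thinning, with exact binomial intervals. Right, CHEK1 in CPM within each phase, with exact Poisson intervals; G2/M held 57.8% of wild-type and 35.9% of knockout cells, and CHEK1 was at 49.6 and 39.9 CPM there.

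Across the transcriptome, 611 of 9323 measured genes were at least 2-fold higher in the knockout and 361 at least 2-fold lower. At least 8-fold, these counts were 87 and 11. There were 23 genes under 1 CPM in the wild type and at 20 CPM or more in the knockout, and 0 with the opposite pattern. The 0 depends on the 222 knockout-library cells, which can keep wild-type genes above 1 CPM in these sums. PADI3, at 20.8 CPM in the wild type, was at 0.596 CPM in the other 4449 cells. The 0 therefore does not show that no gene was lost in most knockout cells. The median log2 ratio of all measured genes was -0.05, and other scalings moved it by at most 0.10.

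Interferon-response genes were far higher in the knockout library than any other list. All 20 measured members were at least 2-fold higher, with a median log2 ratio of 4.11 (percentile 100). IFI27, a mitochondrial interferon-induced protein, was at 25.5 CPM in the wild type and 3308 CPM in the knockout. The antiviral RNA sensors OAS1 and OAS2 were at 0.357 and 41.1 CPM and at 0.0622 and 21.8 CPM, and the membrane protein IFITM1 at 0.178 and 23. Per cell thinned to 12000 UMIs, the list gave a median of 3 UMIs in the wild type and 89 in the knockout, and 99.7% of knockout cells (99.5% to 99.8%) lay above the 99th percentile of wild-type cells. In the 222 knockout-library cells with ATRX near the wild-type level, the median ratio to the wild-type library was 3.91. Leukocyte and microglia markers summed to 0.859 and 0.741 CPM.

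Antigen presentation genes were higher as well, with a median of 2.21 and all 11 measured members at least 1.5-fold higher. The immunoproteasome subunit PSMB9 was at 4.75 and 77.9 CPM, and B2M, the light chain of class I molecules, at 1017 and 5774. HLA-B was at 112 and 1321 CPM and HLA-F at 5.82 and 39.1, although reads may be shared among class I genes. The cytokine and NF-kB list had a median of 1.10, with 7 of 11 members at least 1.5-fold higher and 2 lower. Its members went both ways: NFKBIA, an inhibitor of NF-kB, was at 15.8 and 49.5 CPM, RELB at 3.57 and 12.4 and CSF1 at 3.52 and 11.4, whereas IL11 was at 215 and 46.2. The list median was 0.53 with equal phase weights and 0.67 among members of at least 20 CPM.

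Genes of the response to low oxygen were higher in the knockout, with a median of 0.997 and 15 of 19 members at least 1.5-fold higher. DDIT4, an inhibitor of mTOR signalling, was at 5.39 and 51.5 CPM, NDRG1 at 2.92 and 18.9, the mitophagy receptor BNIP3L at 17.3 and 80.4, and the collagen hydroxylase P4HA1 at 31.1 and 140. Glycolysis genes had a median of 0.39, with 5 of 18 at least 1.5-fold higher, among them LDHA at 9.51 and 31.2 CPM, the lactate exporter SLC16A3 at 165 and 353, ENO2 at 22.1 and 44.0 and ALDOC at 0.398 and 15.7. Metallothioneins had a median of 0.96 over 5 genes, with MT1E at 113 and 504 CPM, MT1F at 5.51 and 18.7, MT1X at 211 and 412 and MT2A at 2765 and 3552, although these paralogs may share reads. The metallothionein median was 0.42 in G1 cells, with 1 member at least 1.5-fold higher and 1 lower, 0.77 in S cells and 1.12 in G2/M cells. The antioxidant and NRF2 list had a median of 0.35, or 0.54 with genes of at least 1 CPM, with the ferritin light chain FTL at 2201 and 5182 CPM, AKR1C3 at 2.82 and 23, and TXNRD1 at 285 and 138. Mitochondrial mRNAs had a median of 0.52, with MT-ND2 at 492 and 994 CPM, MT-ND4L at 65.0 and 131, MT-ND1 at 610 and 1154 and MT-ND4 at 1325 and 2343.

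Mesenchymal and matrix genes included some of the largest differences, with 14 of 33 at least 1.5-fold higher, 4 lower and a median of 0.36. The collagens COL1A1 and COL6A3 were at 2.70 and 236 CPM and at 2.62 and 48.6, the matricellular protein POSTN at 0.158 and 27.9, and the actin-binding protein TAGLN at 2.13 and 43.3. TGF-beta and BMP targets had a median of 0.61, with TGFB1 at 38.4 and 128 CPM, LTBP2 at 7.0 and 17, and SKIL at 17.8 and 40.9. The astrocyte list had a median of 0.82 over the 8 of its 18 genes that were measured. The small heat shock protein CRYAB was at 15.1 and 117 CPM, CST3 at 210 and 371, and FABP7, a fatty acid carrier of radial glia, at 96.1 and 39.9. The astrocyte marker GFAP was not among the measured genes, at 0.0664 and 0.0217 CPM. The astrocyte median was 0.49 with genes of at least 1 CPM and 0.16 with genes of at least 20 CPM. In the 222 cells with ATRX near the wild-type level, the mesenchymal and TGF-beta medians were 0.08 and 0.10.

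The 12 highest ratios were those of CAVIN3, CADM3, LUM, DHRS2, IER3, BASP1, FABP4, OAS2, TUBA3C, ACTG2, POSTN and IFI27. CAVIN3, a caveolar coat protein, had 3 UMIs in the wild type and 32191 in the knockout, a log2 ratio of 13.19 (11.64 to 15.47). CADM3, a cell adhesion molecule, had 2 and 7195 UMIs (11.61, 9.76 to 14.66), and LUM, a matrix proteoglycan, 5 and 8287. DHRS2 was at 0.278 and 192 CPM, the early response gene IER3 at 0.564 and 328, the membrane protein BASP1 at 0.083 and 37.4, and the fatty acid carrier FABP4 at 0.651 and 237. TUBA3C was at 0.162 and 43.4 CPM, although tubulin paralogs may share reads, and the smooth muscle actin ACTG2 at 0.353 and 87.2.

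The 12 lowest ratios were those of PADI2, MARCH10, GFRA1, PADI3, ALPK2, EDN1, DIO2, STXBP6, SOCS2, POU3F2, CCDC80 and AMOT. PADI2 and PADI3, which convert arginine to citrulline in proteins, were at 39.2 and 2.34 CPM and at 20.8 and 2.24 CPM. GFRA1, a receptor of the growth factor GDNF, was at 65.3 and 5.76 CPM, the vasoconstrictor EDN1 at 90.9 and 11.6, and DIO2, which activates thyroid hormone, at 196 and 25. MARCH10, a ubiquitin ligase, was at 50.1 and 3.22 CPM, ALPK2 at 20.02 and 2.17, STXBP6 at 26.1 and 3.44, and SOCS2, a brake on cytokine signalling, at 51.2 and 7.78. POU3F2, a neural transcription factor, was at 34.4 and 5.25 CPM, CCDC80 at 131 and 20.5, and AMOT, a regulator of YAP, at 34.9 and 5.63. In the 222 cells with ATRX near the wild-type level, these 12 genes stood at a median of 41.0% of the wild-type level. PADI2 was at 27.9 CPM and PADI3 at 34.4 there, whereas MARCH10 was at 6.99, DIO2 at 41.4 and CCDC80 at 30.1.

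Heterochromatin factors and histone chaperones, the class to which ATRX belongs, were lower, with a median of -0.36 over 26 genes (percentile 0.40), 6 at least 1.5-fold lower and 1 higher. The methyltransferases EHMT1 and EZH2 were at 39.2 and 22.3 CPM and at 99.5 and 58.0, MORC3 at 19.2 and 11.2, and the histone variant H2AFY at 237 and 146. Zinc finger genes, many of which repress transposons, had a median of -0.22 over 162 members (percentile 0), with 25 at least 1.5-fold lower and 7 higher. Examples were ZNF655 at 46.8 and 22.1 CPM, ZNF480 at 28.6 and 13.5, ZNF496 at 10.7 and 5.25, and ZNF22 at 66.3 and 134. In the 222 cells with ATRX near the wild-type level, the medians of both lists were -0.05 and 0.04. With the median of neighbouring genes subtracted, 2 heterochromatin genes were at least 1.5-fold lower and the list median was -0.33, and with median-of-ratios factors the zinc finger median was -0.13.

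The repair and telomere lists lay within the range of matched random lists, and with median-of-ratios factors their medians were -0.12, -0.11 and -0.05. Homologous recombination genes had a median of -0.22 (percentile 10.2), with FANCD2 at 23.4 and 42.7 CPM, RMI1 at 25.5 and 15.1 and XRCC2 at 23.2 and 14.9. The neighbours of FANCD2 and RMI1 were shifted by 0.92 and -0.74. End-joining genes had a median of -0.21 (percentile 13.3), with PARP1 at 222 and 124 CPM, LIG3 at 15.5 and 9.40 and MAD2L2 at 70.6 and 104. Telomere maintenance genes had a median of -0.14, with NR2F2 at 138 and 31.0 CPM, the dyskerin gene DKC1 at 196 and 123, NHP2 at 456 and 289 and ZNF827 at 14.1 and 9.40.

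Over all cells, the remaining lists had medians near 0 with members on both sides. Neural stem genes had a median of -0.19, with the stem cell factor SOX2 at 136 and 44.2 CPM, HEY1 at 2.61 and 13.1 and HES4 at 77.0 and 222. Of 6 measured proneural genes, SOX11 was at 62.8 and 17.0 CPM and SOX4 at 118 and 298, DLL3 at 7.84 and 11.6 and MAP2 at 10.2 and 12.7, with a list median of 0.19. Medians were -0.01 for cholesterol synthesis (SC5D at 8.84 and 13.9 CPM, SREBF2 at 7.96 and 11.3) and -0.07 for ATF4 and the unfolded protein response (XBP1 at 33.3 and 64.8, PSAT1 at 83.5 and 43.9, HERPUD1 at 22.3 and 35.0, PHGDH at 95.2 and 135). The signs of these 4 medians changed under some alternatives. Medians were -0.17 for heat shock and immediate early genes (JUNB at 9.42 and 39.8 CPM, KLF2 at 34.7 and 81.7, EGR1 at 10.3 and 22.0) and -0.15 for imprinted genes (PEG10 at 508 and 193, MEST at 114 and 38, SNRPN at 12.5 and 21.9, PHLDA2 at 256 and 354). In G1 cells alone the cholesterol list had a median of -0.51 (percentile 0.21), with 8 of 18 members at least 1.5-fold lower and 0 higher. The ATF4 list had -0.39 there (percentile 0.35), with 5 of 22 lower and 0 higher. These medians were -0.03 and -0.08 in S cells and 0.02 and -0.04 in G2/M cells. Also in G1 cells, the ratios of HERPUD1, EGR1 and PHLDA2 were negative, at -0.12, -0.38 and -0.19. These G1 values use the main scaling. TMM factors raised the CHEK1 ratio in G1 cells from -0.13 to 0.11. The G1 medians therefore depend on scaling, and G1 ratios near 0 have no settled sign.

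**Figure D2:**
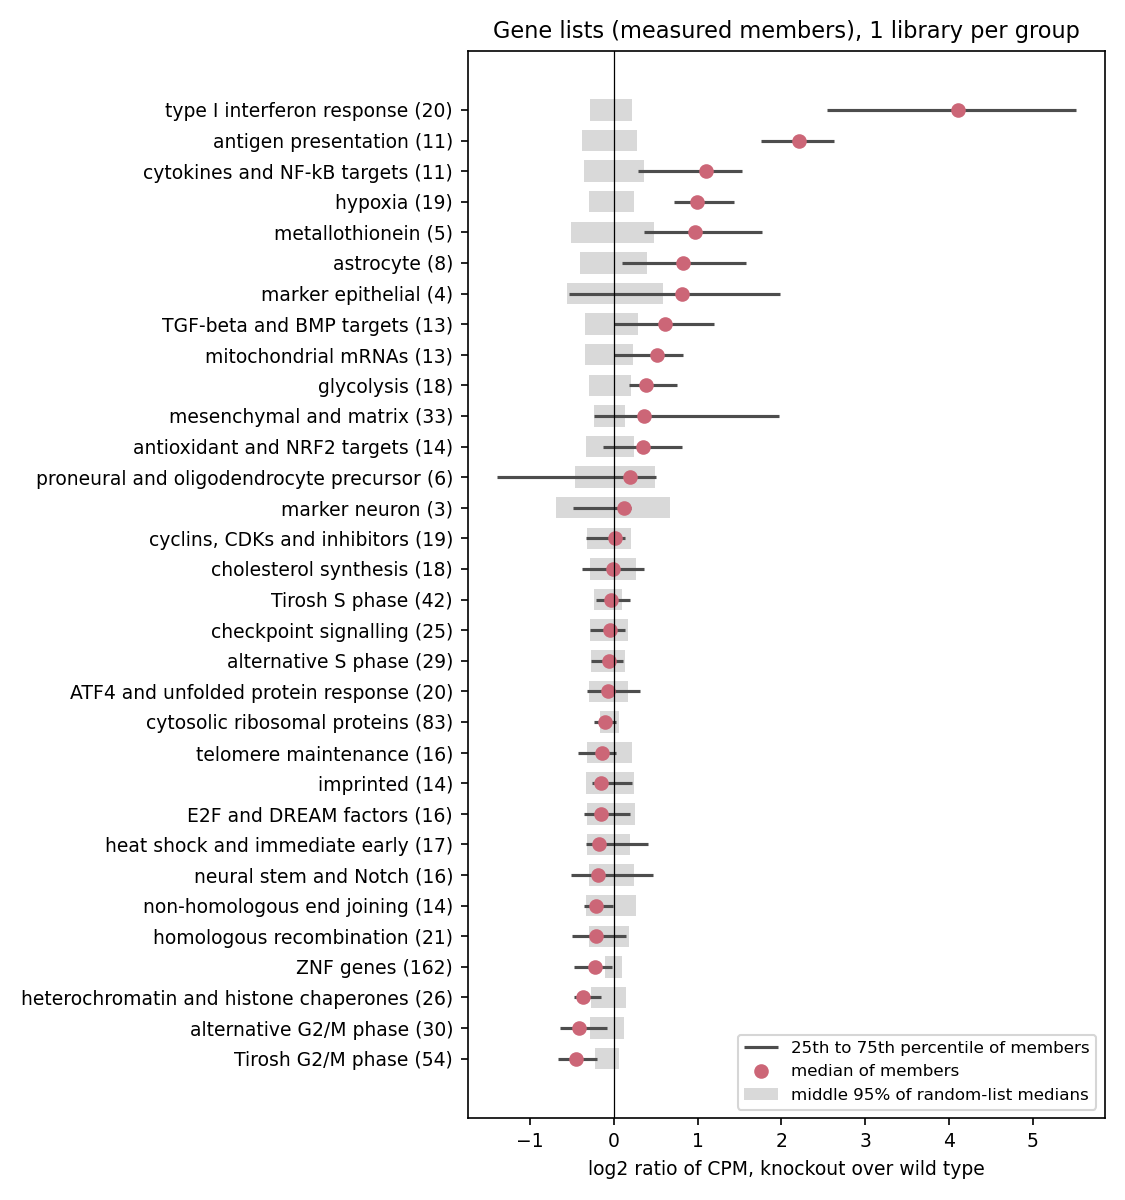
Median log2 ratio of CPM, knockout over wild type, of each list reported here with at least 3 measured members (number in brackets), with lines for the 25th to 75th percentile of members and grey bars for the middle 95% of matched random-list medians. The interferon list stands at 4.11 and the first G2/M list at -0.45.

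Markers of other cell types were compared in both libraries. Epithelial genes went both ways, with KRT8 at 96.7 and 350 CPM, CLDN4 at 6.95 and 35.5, KRT18 at 246 and 211 and KRT19 at 8.16 and 2.93, and a median of 0.82, or 1.86 with genes of at least 20 CPM. The 3 measured neuronal markers had a median of 0.12, with NEFL at 211 and 260 CPM, SYT1 at 23.6 and 25.6 and GAD1 at 23.5 and 11.1. The NEFL and SYT1 ratios were -0.17 and -0.09 in G1 cells with the main scaling, which does not settle signs near 0 there. The oligodendrocyte marker CNP was at 37.0 and 40.1 CPM. Endothelial and mural markers were no higher than RGS5 at 1.94 and 1.58 CPM, and of the erythroid markers HBB was at 1.15 and 0.564 CPM.

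**Figure D3:**
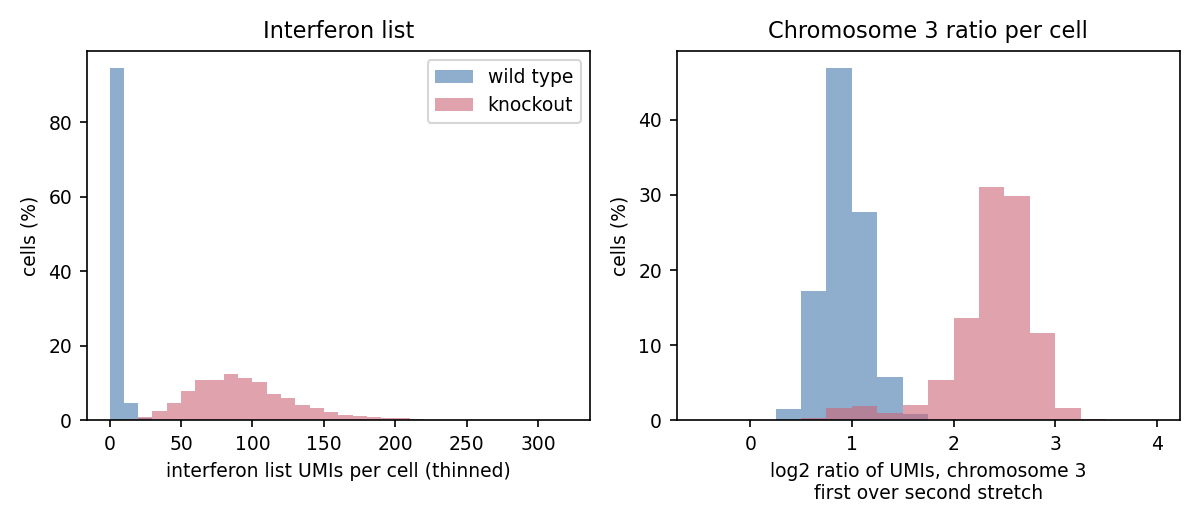
Left, UMIs of the interferon list per cell thinned to 12000 UMIs, as percent of cells in each library, with medians of 3 and 89. Right, log2 ratio per cell of UMIs from the first over the second stretch of chromosome 3, with the wild type in blue and the knockout in red; 222 knockout-library cells lie at or below the 99th percentile of wild-type cells.

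Genes were also compared by chromosome, which the design had set as a check. Chromosome medians were lowest for 21 at -0.40 and 9 at -0.39, followed by 5 at -0.28 and 7 at -0.25, and highest for 8 at 0.20 and 3 at 0.16. Along chromosome 3, 204 genes from 3.13 to 51.7 Mb had a median of 0.55, the next 110 genes up to 116 Mb had -0.75, and the last 243 had 0.06. Ribosomal proteins had a median of -0.11 over 83 genes, and their lowest members lay in lower stretches, with RPS7 on chromosome 2 at 3527 and 1459 CPM and RPL29 and RPL24 on chromosome 3 at 3209 and 1390 and at 2496 and 1118. RPL39L was at 45.9 and 87.5 CPM. Several named genes lay in such stretches. With the median of 50 neighbouring genes subtracted, ratios near 0 or of the other sign were left for RRM2 (0.18), E2F6 (0.01), FANCD2 (-0.06), RMI1 (-0.01), EXO1 (-0.08), NEFL (-0.09) and PHLDA2 (0.07). Smaller ratios of the same sign were left for FANCI (-0.15), PSAT1 (-0.23), TP53BP1 (0.21), WDR76 (0.43), CCNB1 (-0.47), EHMT1 (-0.46), MORC3 (-0.45), ZNF496 (-0.43), CKS2 (-0.73) and SOX11 (-1.05), among others. These included PARP1 (-0.51), XRCC2 (-0.41), MCM2 (-0.29), RAD1 (-0.40), TK1 (0.29), MAP2 (0.17), RPS7 (-0.45) and RPL24 (-0.46).

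**Figure D4:**
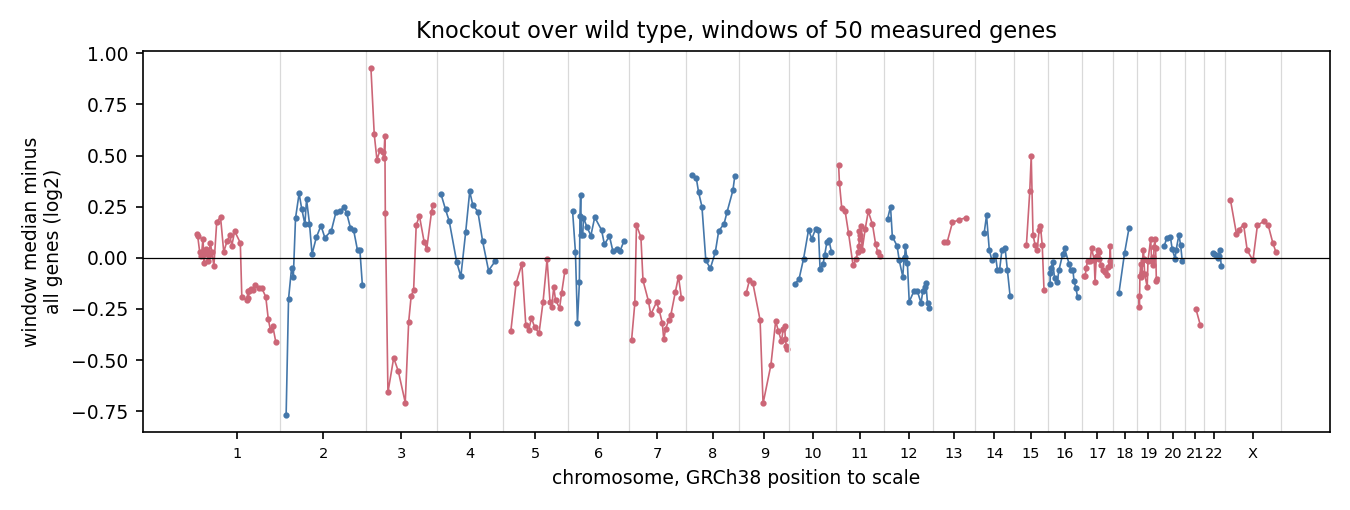
Median log2 ratio, knockout over wild type, of windows of 50 neighbouring measured genes minus the median of all genes, by GRCh38 position to scale, with colours alternating by chromosome. Windows range from -0.77 on chromosome 2 to 0.93 on chromosome 3.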

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

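The search of barcodes below the cell call was chosen after the data were seen. Haemoglobin transcripts appeared in barcodes that hold no called cell and that none of the comparisons used. In barcodes with 1 to 49 UMIs, HBB made up 12249 CPM in the wild-type library and 13913 CPM in the knockout library, against 1.15 and 0.564 CPM in the called cells. These barcodes held 99361 and 105280 HBB UMIs, and other blood transcripts stood at like counts in both libraries, with HBD at 6202 and 6649, ALAS2 at 650 and 668 and IGHM at 143 and 135. Near-empty barcodes, used here only as the profile of free RNA, held a median of 2019 UMIs in the wild type and 1346 in the knockout and 29.3% and 21.3% of all UMIs. No explanation was tested for these signals.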

How the results depend on the processing

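Alternatives that removed the cells with the highest Scrublet scores, the cells with few mitochondrial UMIs or the 222 cells with a wild-type-like chromosome 3 ratio, or that subtracted neighbouring genes, were chosen after the data were seen. No alternative turned the direction of the ATRX, G2/M list or overall CHEK1 ratio or of any phase difference. Removing Scrublet-called doublets had no effect to measure because 0 cells were called. The ATRX ratio of -1.75 became -1.67 with TMM, -1.65 with median-of-ratios factors, -1.78 with per-cell means, -1.70 with thinned cells, -1.79 with equal phase weights and -1.93 without the 222 cells. The CHEK1 ratio of -0.27 became -0.19 with TMM, -0.17 with median-of-ratios factors and -0.21 with equal phase weights, and it was -0.31 with neighbouring genes subtracted. Within phases, TMM gave CHEK1 0.11 in G1 cells, against -0.13, and -0.07 in S cells, against -0.17. The S list median of -0.028 reversed to 0.049 with TMM, 0.069 with median-of-ratios factors and 0.0080 with neighbouring genes subtracted; it was -0.052 with totals free of mitochondrial and ribosomal protein genes and -0.0035 with equal phase weights. The G2/M list median of -0.45 became -0.37 with TMM, -0.35 with median-of-ratios factors, -0.47 with those restricted totals, -0.47 with per-cell means, -0.14 with equal phase weights, -0.53 with neighbouring genes subtracted and -0.47 without the 222 cells. Genes at least 2-fold higher and lower numbered 1227 and 605 at a mean of 1 CPM or more and 241 and 219 at 20 CPM or more, because fewer or more genes were counted, and stayed within 1.5 times of 611 and 361 in the other settings. The G1 difference of 16.8 points was 13 without thinning, 12.7 with other lists and 14.9 at 1/2 of the UMI minimum. The S difference of 5.12 points was 9.89 without thinning and 9.32 at the lower minimum, and the G2/M difference of -22.0 points was -16.8 with other lists and -24.2 at the lower minimum. The shares themselves moved more with other lists. G2/M then held 35.7% of wild-type and 18.97% of knockout cells, against 57.8% and 35.9%. S held 57.5% and 61.6%, against 33.9% and 39.03%. Whether most wild-type cells were called G2/M or S thus depended on the lists. Except for the gene counts, the cause was not tested. No paired analysis was possible because each group holds 1 library. Depth limits genes below about 5 CPM and the G1 comparison of CHEK1, which rests on 508 wild-type cells.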

Other observations

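Of the tests here, the shuffled gene order and the removal of strongly different genes were set before their results were seen, and the others were chosen after. Histone genes with HIST symbols, a family noticed in the data, were lower in the knockout. The symbols do not separate replication-dependent genes from others, and how well these mRNAs were captured was not tested. Their median log2 ratio was -1.12 over 21 measured genes, 13 at least 2-fold lower and 0 higher, and it was -1.33 within S-phase cells and -0.14 in near-empty barcodes. HIST1H4C, a core histone H4 gene, was at 4311 CPM in the wild type and 1945 CPM in the knockout. S100A2, a calcium-binding protein, was at 296 and 3677 CPM, and SPANXB1, normally a testis gene, at 0.328 and 27.6 CPM. CAV1, CAV2 and CAVIN1, which build caveolae with CAVIN3, were lower, with log2 ratios of -1.13, -1.18 and -0.94, while CAVIN3 was higher.

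The knockout library held 222 cells (4.75%, 4.16% to 5.40%) whose ratio of the chromosome 3 stretches lay at or below the 99th percentile of wild-type cells. They were picked by that ratio and not by ATRX, and 1.01% of wild-type cells lay above that limit. CAVIN3 was at 11.1 CPM in them and 122 CPM in the rest. G2/M calls made up 57.7% of them (50.9% to 64.2%), against 34.8% of the other 4449 cells. G1 calls made up 18.0% of them (13.2% to 23.7%), against 25.4% of the rest and 8.25% of wild-type cells. S calls made up 24.3% (18.8% to 30.5%), against 39.8% and 33.9%. PADI2 was at 27.9 CPM in them and 1.04 CPM in the rest, PADI3 at 34.4 and 0.596, CCND1 at 560 and 296, and CCNB1 at 222 and 122. Other genes stayed far from the wild type in them, with MARCH10 at 6.99 CPM, DIO2 at 41.4 and CCDC80 at 30.1, and the 12 lowest genes kept a median of 41.0% of the wild-type level. CHEK1 was at 39.1 CPM in them and 43 CPM in the rest, both below the wild type. Outside chromosome 3, the 41 shifted windows had a median absolute shift of 0.06 in these cells. The windows were chosen by their shift in the whole library, which fixes the larger value in the rest, and across these overlapping windows the shifts of the 222 cells still correlated with those of the library (Pearson r = 0.388). The hypoxia list had medians of 0.942 and 1.003 relative to the wild type. The medians of heterochromatin factors were -0.05 and -0.38, and those of zinc finger genes 0.04 and -0.24. Other lists lay further from the wild type in the 222 cells than in the rest, among them neural stem genes at 0.50 and -0.23 and the ATF4 list at 0.28 and -0.09.

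ATRX counts remained in the knockout library. In the 222 cells the log2 ratio to the wild type was -0.023 (-0.085 to 0.038), and they held 16.1% of the library's ATRX UMIs. This goes with cells that kept ATRX transcripts and does not show working ATRX. In the other cells 26.2% of the wild-type level remained, whereas the 12 lowest genes kept a median of 11.4%. Only 1.01% of wild-type cells had a chromosome 3 ratio as high as these other cells, which argues against wild-type cells as the source there. The 12 genes were picked as the lowest in this library, so their level adds no separate support. Free RNA would supply 0.975% of the ATRX UMIs per cell and so argues against that source. Transcription of an altered ATRX gene stays open and was not tested.

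Interferon genes were higher in the knockout library. Thinned cells kept a median log2 ratio of 4.09, and leukocyte markers summed to 0.741 CPM, which argue against depth and against RNA from immune cells. In the 222 cells with ATRX near the wild-type level the median was 3.91, which argues against a lower ATRX count in the same cell as the whole cause. The count does not show working ATRX, so loss of ATRX function in these cells was not tested. Free RNA would supply 5.75 UMIs of IFI27 per droplet, against 174 counted per cell in that set. Signals between cells of the knockout culture, a difference in culture or handling, and an earlier event shared by both kinds of cell stay open and were not tested.

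Runs of neighbouring genes were shifted together, with 53 of 340 windows over 0.3 from the median of all genes. In 1000 shuffled gene orders at most 2 windows passed that size, and 50 of the 53 kept a shift over 0.2 without genes at least 2-fold apart, which argue against chance and against a few strong genes. Abundant genes followed their less abundant neighbours with a slope of 1.08 (0.857 to 1.34 over resampled chromosomes), in line with a difference in DNA copy number between most knockout cells and the wild-type culture. Regional control of transcription would also give such a slope, and DNA was not analysed here. As the shifts, the lower ATRX count and the lower G2/M share occurred together in most knockout cells, their effects are not separated by these libraries. Some cell cycle differences were also found in the 222 cells. Of these, 18.0% were called G1 (13.2% to 23.7%), against 8.25% of wild-type cells, and their CHEK1 ratio was -0.40 (-0.53 to -0.28).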
